A study of Caenorhabditis elegans with 2 samples.

How the data were processed

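Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody against GFP on whole hermaphrodite L1 larvae of the Caenorhabditis elegans strain OP506, which carries the integrated transgene wgIs506 in an unc-119 mutant background and makes XBP-1 with a GFP-FLAG tag at its C-terminus. 1 label field gives the antibody as xbp-1, while the description gives anti-GFP, which is taken here. Per the labels, animals were collected 6 h after synchronization by bleaching and L1 starvation, chromatin was sheared by sonication, and the 2 libraries are separate biological replicates. Both replicates belong to 1 group. The control that the labels refer to was not used here, so no comparison made here sets a peak against a background measured the same way. Whether the authors' peak calls used that control was not examined.

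For each of the builds ce11 and ce10, the deposited lists hold relaxed regions (peaks and background) for replicate 1, for replicate 2 and for both replicates pooled, and a thresholded list derived from these by the irreproducible discovery rate (IDR), per the file lists deposited with the samples. The aligner, the peak caller and their versions are not given in the sources used here. Each region has a signal value that the authors' caller assigned; its scale is not stated, so it served only to describe, rank or filter regions within 1 list. The deposited q-value column holds -log10 q and reaches 1 shared highest value over many regions, so it was not used to rank. The lists hold no read totals, so depth is unknown, and no interval below covers sequencing error: intervals on shares cover counting error over peaks, genes or windows only.

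Coordinates are those of ce11, which is the same assembly as WBcel235, whose Ensembl annotation and RefSeq sequence were used; ce10 lists were used for counts only. Regions were ranked by signal value. A summit was given to a gene when it lay from 1000 bp upstream to 200 bp downstream of any annotated protein-coding transcript start (promoter window), and 1 summit could serve several genes. Other summits were placed in 5' UTR, coding exon, 3' UTR, intron, non-coding gene or intergenic sequence, in that order. The background for gene lists was the 19973 nuclear protein-coding genes.

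The tests were the two-sided Fisher's exact test for 26 gene lists with Benjamini-Hochberg (BH) adjustment over all of them, a one-sided permutation test with 1000 circular shifts of the summits along each chromosome (the smallest p it can give is 0.000999), a two-sided exact binomial test for chromosome X, and a two-sided exact McNemar test of 13 motifs in windows of 50 bp on either side of the summit against windows centred 500 bp away, adjusted over the motifs. Overlap of replicates required at least 1 bp, with 200 shifts giving the chance level. Intervals of shares are 95% Wilson intervals; for a count of 0 the limit given is instead 3 counts out of the total. The threshold was an adjusted p of 0.05. The word CACGTCA, fixed as a separate motif, is the reverse complement of TGACGTG and was counted once. Lists, motifs, tests and the alternatives were fixed before the data were examined, except where a result is said to have been chosen afterwards. The lists overlap in part: hsp-3 and hsp-4 stand among both the response regulators and the ER chaperones, atf-4, atf-6 and xbp-1 also among the bZIP factors. Also shared are dnj-27 (ER chaperones and disulfide isomerases), dnj-29 (ER chaperones and translocon), atfs-1 (mitochondrial stress and bZIP factors), nhr-23 and nhr-25 (nuclear hormone receptors and hypodermis). Neighbouring genes can also share 1 peak, which then counts for each of them as if independent. Between lists this holds for enpl-1 and imp-2, hsp-110 and rpn-3, dnj-19 and nhr-47, sec-61.A and rps-18, spcs-1 and lonp-1, and ribo-1 and rpn-1, among others. Names without a match in the annotation (6 of the 26 translocon names, and 1 or 2 in other lists) were left out. A gene withheld from the text is not reported here.

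The text names xbp-1, ire-1, atf-6, pek-1, hsp-3, hsp-4 and unc-119 in any case, the genes whose promoter window holds 1 of the 20 strongest peaks, and for each list up to 4 members with the strongest promoter peak and up to 2 without a peak, besides genes that share a peak or belong to more than 1 list. Alternatives were a stricter signal threshold, other promoter windows, the nearest transcript start, other backgrounds, other motif windows and flanks, other overlap rules, and each replicate left out by taking the top regions of the other.

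The procedures were tested on simulated data. All 500 summits planted in promoter windows were given to their gene. In 100 random draws of genes, 1 draw gave a call among the 26 lists. Lists with 60% of members given a peak were called in 77% of trials for lists of 10 to 19 genes and in 98.1% for larger ones. In 2 of 60 sets of random summits the circular shift test fell under 0.05. No motif was called in 20 sets of random summits, while an element planted in 90 of 3000 windows was called (BH-adjusted exact McNemar p = 6.05e-11). The random summits were drawn evenly over the genome, so they lack the G+C difference between real summits and flanks. Motif calls caused by composition are therefore not covered. The random draws of genes likewise did not share peaks between neighbours. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.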

Results

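XBP-1 is the basic leucine zipper (bZIP) transcription factor of the endoplasmic reticulum (ER) unfolded protein response, made in its active form after the ER sensor IRE-1 splices its mRNA. The data map peaks of GFP-tagged XBP-1 on chromatin in L1 larvae of C. elegans collected 6 h after synchronization by starvation, in 2 biological replicates of 1 group. The relaxed lists held 30000 regions for replicate 1, 28535 for replicate 2 and 26088 for the pooled reads, and the thresholded list held 3641 peaks on ce11. These peaks had a median width of 376 bp, which was also the commonest, shared by 2184 of them and by 94.3% of pooled regions. It was therefore not read as the extent of binding. The signal values of the peaks, which are the authors' and rank peaks within the list only, ran from 73.3 to 34888. With 1 group, peak lists alone and no control immunoprecipitation used here, the depth is unknown, and the comparisons are between replicates, between places in the genome and between gene groups.

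The strongest peaks lay at genes that fold, modify or carry secreted proteins. The top peak, with a signal value of 34888, covered X:6091571-6093333 at the promoter of hsp-3 (WBGene00002007), 1 of the BiP-type Hsp70 chaperones of the ER, and its paralog hsp-4 held the peak at rank 9 (II:7352314-7353051, signal 3537). Ranks 2 to 7 lay at pdi-3 (WBGene00003964), a protein disulfide isomerase, which shares the peak with the ubiquilin gene ubql-1 (I:7020789-7021982, signal 27976); crt-1 (WBGene00000802), calreticulin (V:6100208-6101354, 18860.5); pdi-6 (X:7068151-7068885, 17680.9); enpl-1, the ER Hsp90, which shares its peak with the intramembrane protease gene imp-2 (IV:11118773-11119591, 10189.5); pdi-2 (X:4523604-4524766, 9349); and dnj-7, an ER co-chaperone (X:7193797-7194452, 3940). These first 7 peaks had the same rank in each replicate.

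Further down the first 20, secretory genes alternated with others. hsp-60, a mitochondrial chaperonin, shared rank 8 with Y22D7AL.10. syx-5 and memb-1, SNARE proteins of ER-to-Golgi traffic, stood at ranks 10 and 11 (syx-5 together with F55A11.1), and let-607, another bZIP factor gene, at 12. cdc-48.1, the ATPase that extracts proteins from the ER membrane, held rank 14, erd-2.1, a receptor that returns proteins to the ER, rank 15, T14G8.3, an ER Hsp70-family gene, rank 19, and manf-1, a secreted ER stress protein, rank 20. The ribosomal protein genes rpl-3 and rpl-20 (the latter beside Y17G9B.5) held ranks 13 and 16, puf-9, an RNA-binding protein gene, rank 17, and tasp-1 with K01G5.10 rank 18. All 20 summits lay in promoter windows.

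**Figure D1:**
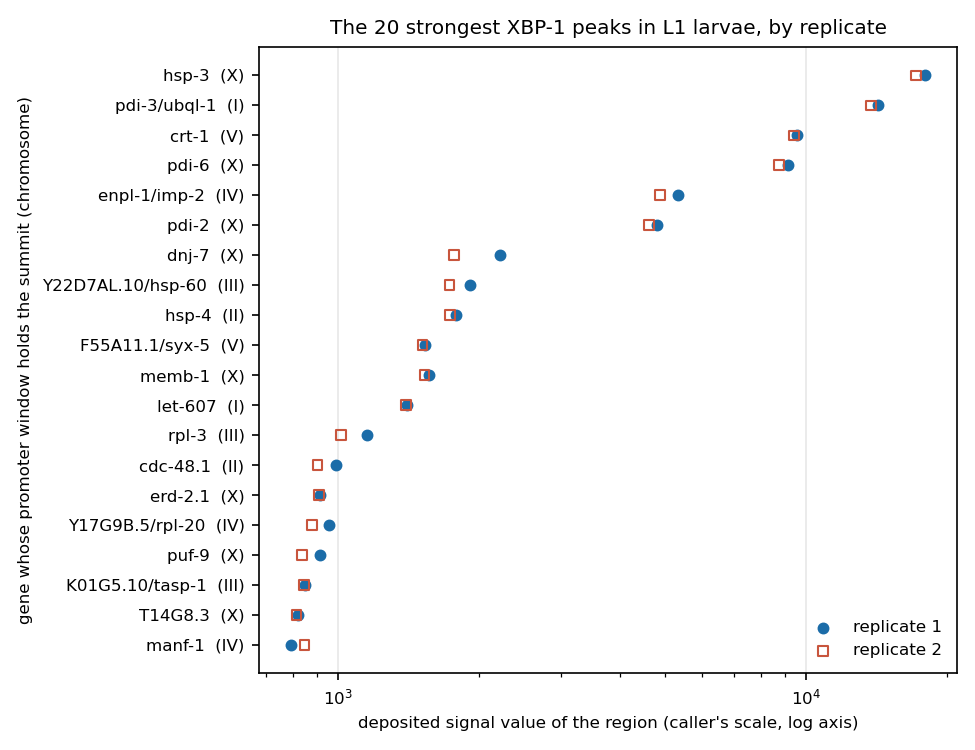
Signal value (horizontal, log axis, on the caller's own scale) of the 20 strongest peaks in replicate 1 (filled circles) and replicate 2 (open squares), 1 row per peak, named by the genes whose promoter window holds the summit. The first 7 rows keep their order in both replicates, from hsp-3 to dnj-7.

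The replicates shared nearly all thresholded peaks. Of the 3641, 3639 (99.9%, Wilson 95% interval 99.80 to 99.98) overlapped a relaxed region in both replicates, against a mean of 8.99% and at most 10.5% for shifted positions. In the stricter comparison with the 3641 strongest regions of each replicate, 3109 (85.4%) were found in both, against a shifted mean of 1.88%. Spearman's rho of the signal values between replicates was 0.884 across 3639 peaks, which are not independent replicates; it was 0.914 among the 100 strongest peaks and 0.186 among the 1641 weakest. Signal values ran from 802.6 to 34888 among the former and only from 73.3 to 135.9 among the latter. A narrow range by itself lowers a rank correlation. The thresholded list was made from these same replicates, so this overlap describes the list and is not an independent test of it.

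Summits gathered just upstream of protein-coding genes. Promoter windows held 2395 of them (65.8%, interval 64.2 to 67.3), 2.56 times the mean of 25.7% at shifted positions (one-sided permutation p = 0.000999, the smallest possible). Coding exons outside promoters held 0.659% against 18.9%, introns 12.2% against 28.0%, and intergenic sequence 18.3% against 21.4%. The median position was -196 bp from the nearest protein-coding transcript start, where negative is upstream, and 80.3% of summits lay upstream of it. The promoter share was 83% among the 100 strongest peaks and 58.2% among the 1641 weakest, and 3092 genes (15.5%) had a promoter peak.

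**Figure D2:**
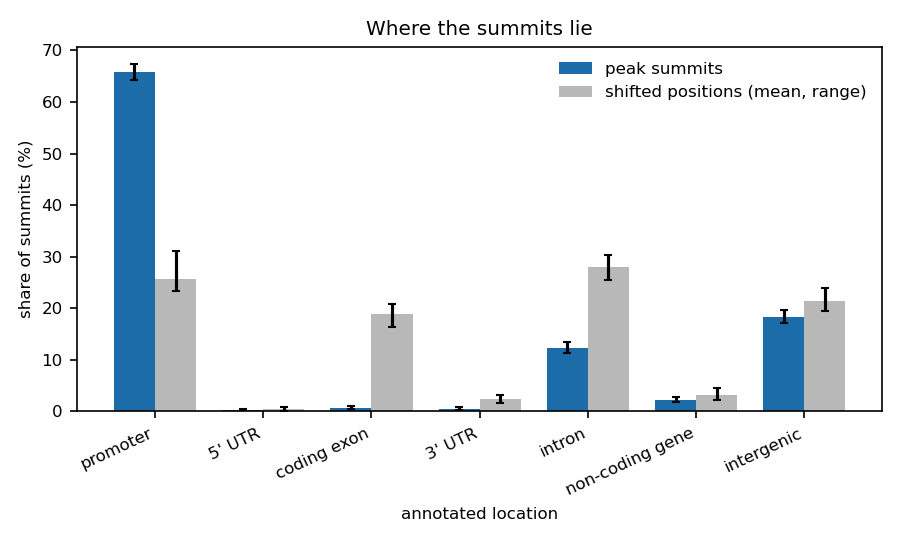
Share of the 3641 summits (blue, with 95% Wilson interval) and of shifted positions (grey, mean of 1000 shifts with lowest and highest) in each annotated class. Promoters hold 65.8% of summits against 25.7% of shifted positions, and coding exons 0.659% against 18.9%.

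Peaks were not spread evenly over chromosomes. Chromosomes III and I had 48.17 and 45.98 peaks per Mb, X 36.91 and V 24.13. X held 654 peaks, 17.96% against 17.67% expected from its length (ratio 1.02, two-sided exact binomial p = 0.648); against its share of protein-coding genes, 13.7%, the ratio was 1.31 (exact binomial p = 4.16e-13). Whether X stands out therefore depends on the expectation used.

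Genes of the unfolded protein response itself mostly had a promoter peak. In the list called response regulators here, 9 of 10 genes had a promoter peak, 90% against 15.4% of other genes. The odds ratio was 49.3 (adjusted p = 1.42e-06 by Fisher's exact test, two-sided, with Benjamini-Hochberg (BH) adjustment over the 26 lists). The 9 genes included the 3 ER stress sensors: pek-1, the PERK kinase (rank 279, signal 516.0), atf-6 (rank 659, 315.7) and ire-1 (rank 1499, 172.7). xbp-1 was the member without a peak. The list is not limited to regulators. It also holds the chaperone genes hsp-3 and hsp-4, which it shares with the ER chaperones, and further genes that are not sensors. With nearest transcript starts the odds ratio was 22.1 (8 of 10).

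The protein folding and degradation machinery of the ER had peaks at most members, but their strength differed. The median ranks of members with a peak were 88 for disulfide isomerases and 738 for ER-associated degradation, against 14 for ER chaperones. Among 14 ER chaperone and calnexin cycle genes, 10 had a promoter peak with a median rank of 14 (odds ratio 13.7, BH-adjusted Fisher's exact p = 1.01e-05); cnx-1, calnexin, and dnj-27 had none. Of 11 disulfide isomerase and ER oxidation genes, 7 had one (odds ratio 9.57, BH-adjusted Fisher's exact p = 0.000679), led by pdi-3, pdi-6, pdi-2 and pdi-1 (rank 88, signal 852.0), while ero-1, the ER oxidase, had none. ER-associated degradation genes had peaks at 10 of 18 (odds ratio 6.84, BH-adjusted Fisher's exact p = 0.000190), with cup-2, a derlin, at rank 39, and none at sel-11 or der-2. Among genes with a relaxed region the disulfide isomerase list no longer passed (odds ratio 3.84, BH-adjusted Fisher's exact p = 0.0748) and the odds ratio of ER chaperones was 5.49. With nearest transcript starts that of ER-associated degradation was 3.51, and among the 1820 strongest peaks that of ER chaperones was 24.6.

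Entry into the ER and traffic out of it were also widely covered. The translocon, signal recognition, signal peptidase and oligosaccharyl transferase list had peaks at 17 of 20 genes (odds ratio 31.1, BH-adjusted Fisher's exact p = 5.00e-11), among them spcs-2 (rank 113), and a peak shared by sec-61.B and trap-3 (rank 130); spcs-3 and sec-11 had none. COPII and COPI vesicle genes had peaks at 24 of 29 (odds ratio 26.4, BH-adjusted Fisher's exact p = 1.16e-14), led by erd-2.1, the cargo receptor gene tmed-10 (rank 179), the coat gene sec-24.1 (rank 210) and the GTPase gene sar-1 (rank 254). sec-24.2 and sft-4 had none. The median rank of the vesicle list was 1598.5. With nearest transcript starts the odds ratios were 5.53 for the translocon list (10 of 20) and 7.85 for vesicle genes (17 of 29), among genes with a relaxed region 9.35 and 9.92, and among the 1820 strongest peaks 14.7 and 7.99. Without replicate 2 that of vesicle genes was 17.4. Phospholipid and fatty acid synthesis genes, in contrast, had peaks at 6 of 30 and did not pass (odds ratio 1.37, BH-adjusted Fisher's exact p = 0.470); cept-2 (rank 267), seip-1 (rank 373), ckb-2 and fat-3 were the strongest, and the desaturase genes fat-1 and fat-2 had none.

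**Figure D3:**
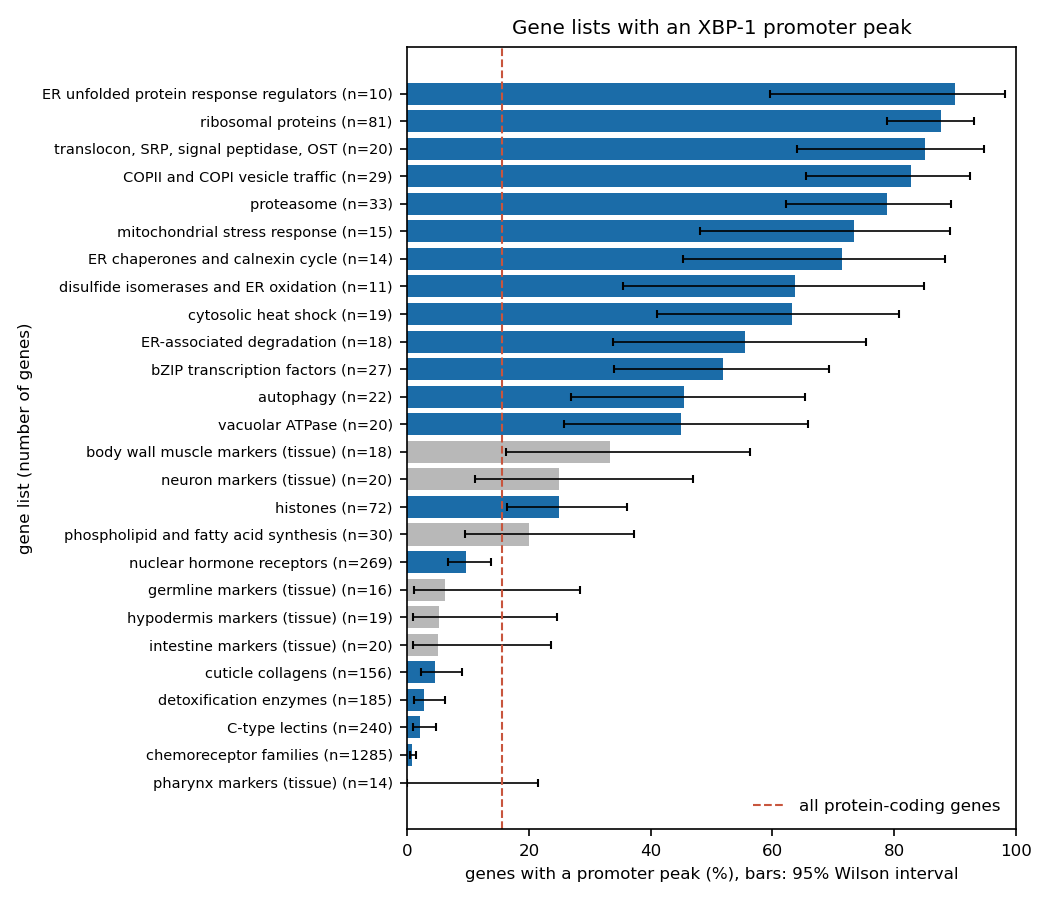
Share of genes with a promoter peak in each of the 26 lists (bars, with 95% Wilson interval and the number of genes), blue where the adjusted p was under 0.05 and grey otherwise; the dashed line is the share among all protein-coding genes, 15.5%. The response regulator list stands at 90%, ribosomal proteins at 87.7% and chemoreceptors at 0.778%.

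Peaks were also common at growth and protein quality genes outside the ER. Ribosomal protein genes had peaks at 71 of 81 (odds ratio 39.7, BH-adjusted Fisher's exact p = 7.27e-46), with rpl-3, rpl-20, rpl-15 (rank 21) and rpl-35 (rank 23) the strongest and a median rank of 477; rpl-11.1 and rps-16 had none. Proteasome genes had peaks at 26 of 33 (odds ratio 20.4, BH-adjusted Fisher's exact p = 9.50e-15), led by rpn-3, whose peak (rank 143) also counts for hsp-110 of the heat shock list, and rpt-2, mitochondrial stress genes at 11 of 15 (odds ratio 15.1, BH-adjusted Fisher's exact p = 2.59e-06), led by hsp-60 and tomm-20, and cytosolic heat shock genes at 12 of 19 (odds ratio 9.39, BH-adjusted Fisher's exact p = 8.34e-06), led by hsp-90 (rank 28), hsp-1 (rank 60) and bag-1 (rank 79). The heat shock regulator hsf-1 had none, nor did dve-1 or clpp-1 of the mitochondrial list. With nearest transcript starts 40 of 81 ribosomal protein genes had a peak and the odds ratio was 5.44, against 8.53 for the proteasome (20 of 33), 4.83 for mitochondrial stress and 4.97 for heat shock genes. Among genes with a relaxed region it was 17.02 for ribosomal proteins, 10.8 for the proteasome and 6.04 for mitochondrial stress.

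bZIP factor genes had peaks at 14 of 27 (odds ratio 5.90, BH-adjusted Fisher's exact p = 2.58e-05), with zip-4 (rank 286), crh-2 and cebp-1 the strongest of that list, which leaves out let-607, and none at atf-2. Autophagy genes had peaks at 10 of 22 (odds ratio 4.56, BH-adjusted Fisher's exact p = 0.00136), led by the ATG8 genes lgg-2 and lgg-1, and vacuolar ATPase genes at 9 of 20 (odds ratio 4.48, BH-adjusted Fisher's exact p = 0.00254), led by vha-12 and vha-8. Among genes with a relaxed region neither passed (BH-adjusted Fisher's exact p = 0.307 and 0.267), and autophagy did not among the 1820 strongest peaks (BH-adjusted Fisher's exact p = 0.0686). Histone genes, led by his-37 (rank 38), had peaks at 18 of 72 and passed narrowly (odds ratio 1.82, BH-adjusted Fisher's exact p = 0.0449). The 18 genes hold only 12 distinct peaks, so the test counts some peaks more than once and the call is uncertain. They did not pass when replicate 1 was left out (odds ratio 1.59), with 2000 bp windows (1.497) or with nearest transcript starts (1.10), and among the 1820 strongest peaks the odds ratio turned to 0.888, while among genes with a relaxed region it was 3.71 (18 of 26, BH-adjusted Fisher's exact p = 0.00442); their copies are near identical, so where reads belong among them is uncertain.

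Environment-facing gene families were largely without peaks. Chemoreceptor genes had a promoter peak at 10 of 1285 (odds ratio 0.0397, BH-adjusted Fisher's exact p = 7.70e-79), C-type lectins at 5 of 240 (0.115, 4.01e-11), detoxification enzymes at 5 of 185 (0.15, 6.54e-08) and cuticle collagens at 7 of 156 (0.255, 5.82e-05), each pair giving the odds ratio and the BH-adjusted Fisher's exact p. col-38 (rank 190) and srh-16 (rank 250) were the strongest of their families; clec-126 and gst-27 led theirs. The C-type lectin odds ratio was 0.0688 without replicate 2 (3 of 240) and 0.0567 with windows of 500 bp, and among genes with a relaxed region it was 0.292, against 0.0848 for chemoreceptors. Nuclear hormone receptors had peaks at 26 of 269 (odds ratio 0.581, BH-adjusted Fisher's exact p = 0.00936), led by nhr-47, whose peak (rank 198) also lies in the promoter window of the heat shock list's dnj-19, and lost their call with a 2000 bp window (0.704, BH-adjusted Fisher's exact p = 0.0591) and with the nearest transcript start (0.992).

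Under the main settings no list of single-tissue markers stood apart from other genes in these whole animals. Of all protein-coding genes, 15.5% had a promoter peak. The shares of body wall muscle (33.3%) and neuron markers (25%) lay above that, and those of the other tissues below. Intestine markers had peaks at 1 of 20 (gut-2), hypodermis at 1 of 19 (ajm-1), germline at 1 of 16 (cgh-1), neurons at 5 of 20 (egl-21 the strongest), body wall muscle at 6 of 18 (act-4 the strongest) and pharynx at 0 of 14, which allows up to 21.4%. None of these 6 lists passed (BH-adjusted Fisher's exact p = 0.377, 0.377, 0.493, 0.262, 0.0622 and 0.182). Assigned to the nearest transcript start, the neuron list passed (odds ratio 8.3), as did body wall muscle (4.42) and the lipid synthesis list (3.20). With windows of 2000 bp the neuron list passed too (3.42), and with windows of 500 bp body wall muscle did (3.42). The muscle list turned the other way without replicate 1 (2 of 18, odds ratio 0.696), in peaks among the strongest of both replicates (0.778), among the 1820 strongest peaks (0.575) and among genes with a relaxed region (0.895), where the neuron (0.821) and lipid synthesis lists (0.615) turned too.

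The core of the UPR element, TGACGTG, lay within 50 bp of 125 summits (3.43%, interval 2.89 to 4.08) against 0.851% of flanking windows, a ratio of 4.03 (BH-adjusted exact McNemar p = 3.85e-14). Among the 100 strongest peaks it was in 14 windows (14%, interval 8.53 to 22.1, flanks 0.5%), and among the next 400 in 12 (3%). In the first 20 peaks it lay close to the summit at crt-1, hsp-4, erd-2.1 and manf-1. In a search of whole peaks, chosen after the values were seen, single copies also lay 80 bp from the summit at hsp-3, 123 bp at dnj-7 and 156 bp at T14G8.3. Distinct promoter peaks with the core numbered 4 of 13 for ER chaperones, 6 of 24 for vesicle traffic, 2 of 11 for response regulators and 0 of 69 for ribosomal protein genes, which allows up to 4.35%.

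Other fixed motifs moved in both directions. GAGAGAGA repeats were in 6.62% of summit windows against 0.687% of flanks (ratio 9.64, BH-adjusted exact McNemar p = 1.32e-38), but in 1% of both among the 100 strongest peaks and in 7.98% against 0.670% among the 1641 weakest. E-boxes (CACGTG) were in 5.47% against 2.16% (2.54, 7.10e-13), CCACGT in 5.93% against 3.10% (1.91, 9.79e-09), the CRE (TGACGTCA) in 1.68% against 0.577% (2.90, 7.57e-05), and the DAF-16 site in 2.44% against 1.13% (2.17, 1.79e-05), each pair giving the ratio and the BH-adjusted exact McNemar p. GATA sites were rarer at summits (3.32% against 8.80%, ratio 0.378, BH-adjusted exact McNemar p = 2.34e-20). The C/EBP site (3.07, BH-adjusted exact McNemar p = 0.00849) and the heat shock element (0.517, BH-adjusted exact McNemar p = 0.0374) each lost the call when either replicate was left out (ratios 2.56 and 2.63 for C/EBP, 0.717 and 0.679 for the heat shock element), and both lost it among the 1820 strongest peaks (3.2 and 0.786). C/EBP also lost it in windows of 25 bp (4.33, BH-adjusted exact McNemar p = 0.0708), and the heat shock element in windows of 100 bp (0.933) and with flanks 300 bp away (1.03). AP-1, SKN-1, ERSE and ERSE-II did not pass (BH-adjusted exact McNemar p = 0.757, 0.596, 0.325 and 1). Summit windows were 47.2% G+C against 36.2% in flanks, and the motif tests did not match composition. The calls for the E-box, CCACGT, GATA and the other motifs were therefore not separated from this difference in G+C. Words of 7 bases with 4 G or C bases had a median ratio of 2.04. By ratio CCACGT ranked 418 of 2045 words of 6 bases. TGACGTG ranked 375 of 3182 words of 7 bases, behind G+C-rich words such as AGCGCGC (ratio 16.9) and GAGACGC (12.8).

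**Figure D4:**
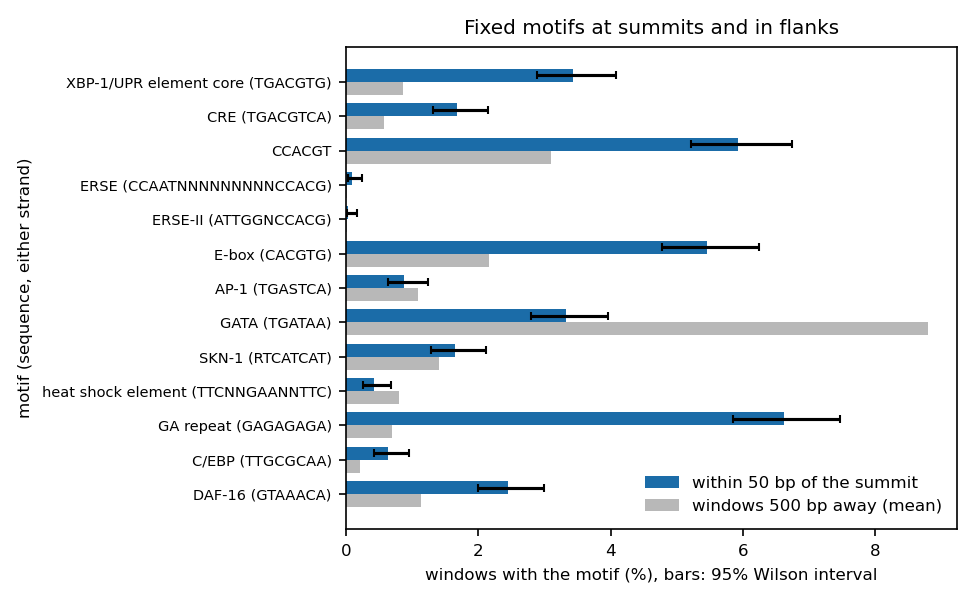
Share of windows holding each fixed motif on either strand, within 50 bp of the summit (blue, with 95% Wilson interval) and in windows centred 500 bp away (grey, mean of both sides). TGACGTG stands at 3.43% against 0.851%, and GATA at 3.32% against 8.80%.

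Summits were also more frequent near tRNA, snoRNA, snRNA and miRNA genes than at shifted positions. Of the 3641 summits, 184 (5.05%) lay within 200 bp of a tRNA gene, 18.3 times the shifted mean, reaching 195 of 612 tRNA genes (31.9%). snoRNA genes had 85 summits (12.2 times, 24.6% of genes reached), snRNA genes 27 (12.2 times, 18.6%) and miRNA genes 13 (3.01 times, 4.60%). Each class had a one-sided permutation p of 0.000999, the smallest possible, and a BH-adjusted permutation p of 0.00125. Among the 1820 strongest peaks, an alternative chosen after seeing the data, miRNA genes did not pass (2.37 times, BH-adjusted permutation p = 0.0762). The 20 rRNA genes had 0 of the 3641 summits, which allows up to 0.0824%, against a shifted mean of 0.0173%. This count therefore does not set them apart from shifted positions. tRNA and snRNA genes have near-identical copies, so the gene a peak is placed at is uncertain.

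At xbp-1, the gene the tagged transgene supplies, and unc-119, the gene mutated in the strain, the density of peaks depended on the list and the window. xbp-1 (III:4193809-4195358) had 0 thresholded peaks within 10 kb and 1 within 20 kb, a density at percentile 46.1 of windows around protein-coding genes. That percentile was 23.5 within 10 kb and 72.2 within 50 kb, and 83.5 within 20 kb without replicate 1. Of relaxed regions within 10 kb, the pooled list held 0 (percentile 3.66), replicate 1 held 1 (10.03) and replicate 2 held 1 (5.73). In wider windows they were dense, with 14 pooled regions within 20 kb (percentile 72.5) and 42 within 50 kb (89.6). unc-119 (III:10902641-10908935) had 3 thresholded peaks within 20 kb, at percentile 76.7 (91.6 within 10 kb), and none in its promoter window.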

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

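Taking as many pooled regions as the ce10 thresholded list holds, leaving out each replicate for the small RNA genes and the xbp-1 and unc-119 loci, and the small RNA test on the strongest peaks were chosen after seeing the data; the others were planned. Promoter enrichment, the UPR element core, GATA, the E-box and the ER, translocon, vesicle, ribosomal and proteasome lists kept their direction and call under every alternative that gave a value, except the disulfide isomerase list, but their size did not hold: with nearest transcript starts the odds ratio fell from 39.7 to 5.44 for ribosomal, 31.1 to 5.53 for translocon, 26.4 to 7.85 for vesicle and 20.4 to 8.53 for proteasome genes. For the motifs, no alternative matched the base composition of summit and flanking windows. The odds ratio had no finite value for translocon genes with 2000 bp windows (20 of 20) and response regulators among genes with a relaxed region (9 of 9). The ce10 list held 4392 peaks, 751 more; ce10 pooled regions at or above the lowest ce11 thresholded signal numbered 3640, and the lowest thresholded signal was 59.4 on ce10 and 73.3 on ce11. Depth is unknown, so what it limits could not be given.

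Among the 1820 strongest peaks, genes with a promoter peak numbered 1854, 100% of peaks were in both replicates, rho was 0.909, autophagy fell to an odds ratio of 2.88, miRNA genes to 2.37 times, and histones (0.888), muscle (0.575), the X ratio by length (0.964) and SKN-1 (0.8) reversed; fewer peaks were tested. Shared peaks were 97.5% with summits within 100 bp, 85.36% with reciprocal overlap of 50% and 85.39% in the top regions of each replicate, and rho with nearest summits was 0.872. For X against gene number the ratio was 1.31. With 2000 bp windows histones gave 1.497, nuclear hormone receptors 0.704 and neuron markers 3.42; with 500 bp windows body wall muscle gave 3.42; with nearest starts lipid synthesis gave 3.20, histones 1.10, nuclear hormone receptors 0.992, muscle 4.42, neurons 8.3 and hypodermis a reversed 1.03. Against genes with a relaxed region disulfide isomerases gave 3.84, autophagy 1.83, vacuolar ATPases 2.11 and histones 3.71, and muscle (0.895), neurons (0.821) and lipid synthesis (0.615) reversed; against genes with a name-number symbol histones gave 1.35. With as many pooled regions as the ce10 list, muscle gave 3.07; in peaks among the strongest of both replicates it reversed to 0.778. With flanks 300 bp away the heat shock element gave 1.03 and AP-1 1.03; AP-1 also reversed with flanks 1000 bp away (1.02), windows of 100 bp (1.06) and without replicate 2 (0.602 to 1.12 without a replicate), and ERSE-II with windows of 25 bp (0). Around xbp-1 the percentile was 23.5 within 10 kb, 72.2 within 50 kb and 68.5 to 83.5 without a replicate; around unc-119 it was 91.6 within 10 kb and 58.5 to 76.7 without a replicate. Without a replicate histones gave 1.59 to 2.12 and muscle 0.696 to 2.76. The cause was not tested for any of these unless given.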

Other observations

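The tests of rank and of the UPR element at ER folding genes, the element at housekeeping genes, the joining of ER chaperones and disulfide isomerases into 1 set, the words other than the fixed motifs and the peak classes they were counted in were chosen after the result was seen, and the gap around xbp-1 had been noticed before its tests. The words TGACGTG and TACCGTA were more frequent at the 100 strongest than at the 1641 weakest peaks. Of 3204 words present in at least 1% of the windows of the 100 strongest and 1641 weakest peaks together, CTGACGT (13 windows against 1.40% of the 1641 weakest), TACCGTA (14 against 2.07%) and TGACGTG (14 against 3.17%) ranked 1, 2 and 5 by p, and CTGACGT overlaps TGACGTG (BH-adjusted two-sided Fisher's exact p = 8.41e-05, 0.000262 and 0.00705). The counts by gene class cover peaks of any rank and only describe. TGACGTG lay at 5 of 20 ER folding peaks and 6 of 24 vesicle traffic peaks, where TACCGTA lay at 0 and 0 (allowing up to 15% and 12.5%). TACCGTA lay at 17 of 69 ribosomal protein peaks (24.6%, interval 15.99 to 35.96) and 4 of 28 proteasome peaks, where TGACGTG lay at 0 and 0 (allowing up to 4.35% and 10.7%). Over all 3641 peaks TACCGTA lay at 3.08% and TGACGTG at 3.43%. The limits just given for each word lie above its share over all peaks. These counts of 0 therefore do not set the classes below all peaks. Among the first 100 peaks TACCGTA was at rpl-3, rpl-20, rps-1, rps-20, rpl-11.2, the elongation factor gene eef-1A.1 and cox-5A, but also at the secretory genes syx-5 and serp-1.1 and at lsy-12, cbp-1 and drap-1, among others. TGACGTG was at crt-1, hsp-4, erd-2.1, manf-1, dnj-28, dnj-20, pdi-1 and nucb-1, but also at pab-2 and ntl-11, and 2 of its 14 peaks were in no promoter window. Of the 184 peaks at tRNA genes, 0 held either word, which allows up to 1.63%.

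A broader set of peaks held GAGACGC and GACGCAG, in 12.33% and 12.22% of all summit windows against 0.961% and 0.975% of flanks. Among 474 words with the same number of G and C bases their ratios, 12.8 and 12.5, ranked 4 and 5, where the median was 3; TGACGTG, at 4.03, ranked 90 of 749 with a median of 2.04. They were at 5 and 4 of the 184 tRNA peaks.

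ER folding genes (ER chaperones and disulfide isomerases together) held the strongest peaks: 17 of 24 had a peak, with a median rank of 19 against 477 for 71 ribosomal protein genes. The set was joined because its members led the ranking, so the p of this difference (two-sided permutation p = 0.00146) restates what was seen and decides nothing about height set by promoter activity, which stays open as expression was not analysed here. G+C content does not account for the pattern, since the median at ER folding summits was -4.95 percentage points relative to ribosomal summits (45.5% against 50.5%). Over the whole list, summit G+C was higher at stronger peaks, 51.1% among the 100 strongest against 45.9% among the 1641 weakest. Binding through the UPR element stays open too: 5 of 20 ER folding and 0 of 69 ribosomal peaks held TGACGTG near the summit, but these counts were seen first, so their Fisher's exact p = 0.000374 decides nothing. The 5 had a median rank of 80 and the other 15 of 22, and 10 of the 20 held it anywhere in the peak, a count not adjusted for peak width. Vesicle traffic peaks held it near the summit as often (6 of 24). Those 6 stood at ranks 15, 254, 743, 1628, 2726 and 2933. The median rank over all 24 vesicle genes with a peak, with or without the core, was 1598.5.

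Peaks lay at most promoters of the ribosomal protein, proteasome and mitochondrial stress lists, but at only 9 of 20 vacuolar ATPase genes. The lists other than the vacuolar ATPases were joined under the name housekeeping, although the mitochondrial list holds stress response genes. Of the 108 summit windows of the joined lists, 0 (0%, allowing up to 2.78%) held TGACGTG. This argues against the exact core within 50 bp of the summit as what these peaks share. The bound for this test was set after the count was seen. As 15 of 20 ER folding peaks also lacked the core there, the count decides nothing further about the element. Promoter G+C content did not account for the peaks at ribosomal protein genes, because within deciles of G+C their odds ratio was 38.9 (interval 20.2 to 74.9). Windows shared with a neighbour are not the whole cause: among genes with no other coding start within 2000 bp, 6 of 8 ribosomal protein genes had a peak (odds ratio 29.8, interval 5.32 to 302), but these are few, and with nearest transcript starts 40 of 81 had one (odds ratio 5.44), so for the others a neighbour's peak stays open. Signal at open chromatin that any tagged protein or the antibody would give was not tested, as no control immunoprecipitation was used here, and no biological explanation other than the element was tested.

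The interval III:4181500-4208130 around xbp-1 held no pooled relaxed region over 26.6 kb, and the 10 kb on either side of the gene stood at percentile 3.66 of windows around genes. Gaps of this length are not rare, as 14.4% of protein-coding genes lay in one at least as long. That share covers all chromosomes and does not match the local density of regions. Around xbp-1 this density was high, with 42 pooled relaxed regions within 50 kb (percentile 89.6 of windows around genes). Chance is therefore neither shown nor excluded as the reason for the gap here. Repeats are an unlikely cause, since the masked share of the gap was 0.660 times that of the chromosome (26.3% against 39.9%). At the chromosome's rate (51.1% of genes), 9 genes with no region would have a probability of 0.00159, but the interval was defined by holding none, so this decides nothing. Replicates 1 and 2 had 1 and 3 relaxed regions there, the best at ranks 9957 and 11566.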
